A study of Homo sapiens with 6 samples.

How the data were processed

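RNA was measured in 6 libraries of BE(2)-M17, a human neuroblastoma cell line. Per the labels' protocols, cells grown with 10% fetal bovine serum received either a control siRNA with no intended target or the hsa-miR-137 mimic, at 100 pmol, by lipid transfection. The mimic is a synthetic RNA that stands in for the mature microRNA. The labels give 3 libraries of each kind, numbered 1 to 3 in each group. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, ribosomal RNA was depleted and paired-end reads of 150 bp were planned at 80 M per sample (M, mega), 40 M in each direction; another label of the same samples names the molecule as polyA RNA.

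The authors deposited FPKM values, in which the fragments of a gene are divided by its length and by the fragments of its library, with 1 column for each library. Per the submitters' processing notes, TopHat2 2.1.0 and Cuffdiff were among the tools, with the genome build GRCh38 (hg38). The gene annotation, the strand setting and the way libraries were scaled are not given in the sources used here. Reads of an antisense gene and its partner, or of near-identical gene copies, therefore cannot be told apart. The table holds 26372 genes, and each of the 6 columns matched the title of 1 sample. FPKM values are not counts, so no count model was used.

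Depth was estimated from low values. In 19 to 31 genes with 1 annotated transcript of at least 3000 nt, the FPKM nearest to that of 1 fragment gave an effective size of about 13.4, 15.0 and 15.3 M fragments for control 1, 2 and 3. The estimates for mimic 1, 2 and 3 were about 12.0, 11.5 and 14.7 M fragments. These sizes depend on the transcript length assumed and are approximate. Ratios between libraries over genes with a mean FPKM under 0.05 put the depths at 0.86 to 1.14 of that of control 1.

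Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested, 13475 in all. Values were log2(FPKM + 0.5), and fold changes are on that scale, which understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Of 24 lists, 22 had at least 5 tested members. MIAT also had an exact permutation test.

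For seed sites, gene symbols were matched to GENCODE release 29 (GRCh38). Of the tested genes, 12675 matched by symbol, 447 by an older symbol and 353 did not match. The longest annotated 3' UTR of 12126 protein-coding genes, each of at least 50 nt, was searched for AGCAATA, which pairs with bases 2 to 8 of the mature microRNA, UUAUUGCUUAAGAAUACGCGUAG. The median log2 fold change of genes with the site minus that of genes without was ranked among the 210 distinct orderings of the same bases. One of these orderings, GCAATAA, is itself a weaker site of miR-137. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for the sequences.

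The test, lists, sites, alternatives and the rule for named genes were fixed before the data were examined. The rule names MIAT, MIR137HG, EZH2, KDM1A, CDK6 and MITF. It adds 10 genes in each direction, by smallest p where none passes, among genes with no overlap between the groups. It also adds 2 members of each list by mean FPKM where none passes. A gene that the rule names is not reported here. The alternatives were other pseudocounts (0.1 and 1), filters, scalings, limma options, set tests, site definitions, a block for the replicate number, and leaving out each library. Leaving out replicate 3 of both groups, and running camera with an estimated correlation and fry under each alternative, were added after the data were seen.

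The gene, list and site steps were tested on simulated data. In 13475 simulated genes of the comparison of mimic with control, 68.7% of genes changed by 1.5-fold were recovered, 98.5% of those changed by 2-fold and 98.5% of those changed by 4-fold, with 8 false calls. A simulated list shift of 0.2 gave an adjusted p of 1.8e-06 from camera, with 0 other lists called. A simulated site shift of -0.1 was recovered as -0.11. Simulated genes varied independently, with no correlation between genes and no structure among libraries, unlike these data. The recovery and the false calls thus check the steps and do not give the power or error rate for these data. Groups of 3 libraries allow no exact p under 0.1.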

Results

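The series measured RNA by sequencing in BE(2)-M17 neuroblastoma cells, 3 libraries labelled control and 3 labelled miR-137 mimic. Total FPKM per library lay between 526374 and 579087, and 13404 to 13501 genes reached an FPKM of 0.5 in each library. The gene with the largest share was RPS27 in each of the 6 libraries, at 1.42% to 1.80% of the total. RNA18S5, a ribosomal RNA, was at 0.90, 2.18 and 0.68 FPKM in control 1, 2 and 3 and at 2.32, 7.87 and 92.5 FPKM in mimic 1, 2 and 3.

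The title of the series names the long noncoding RNA GOMAFU, whose gene symbol is MIAT, as induced by miR-137, and the first question was whether MIAT differed between the groups. MIAT, at chromosome 22, 26646428 to 26676475 on the plus strand of GRCh38 and annotated as a lincRNA, was at 29.5 ± 4.58 FPKM (SD, n = 3) in libraries labelled mimic and 27.8 ± 3.91 FPKM (SD, n = 3) in those labelled control. The log2 difference was 0.08 with a 95% interval from -0.22 to 0.38, and limma's adjusted p was 0.999. An exact two-sided permutation test gave p = 0.8, where the smallest p it allows is 0.1. MIAT stood at 30.4, 33.6 and 24.5 FPKM in mimic 1, 2 and 3 and at 26.5, 24.8 and 32.2 FPKM in control 1, 2 and 3. Control 3 thus lay between mimic 1 and mimic 2, and mimic 3 below each control. Reported targets of miR-137 also went against the labels of these libraries, so the difference and its interval hold only for the libraries as labelled. Without mimic 2 the difference was -0.02, without control 2 it was 0.0024, and without control 3 and without mimic 3 it was 0.19 and 0.21. Without both replicates 3, a choice made after the data were seen, it was 0.31 with an adjusted p of 0.135 from limma.

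Reported targets of miR-137 served as a check of the labels, since the mimic itself was not measured and MIR137 is listed at 0. CDK6, a cyclin-dependent kinase of the G1 phase at chromosome 7, 92604921 to 92836594 on the minus strand, has an AGCAATA match in its 3' UTR. It was at 55.9 and 58.0 FPKM in mimic 1 and 2 but at 85.1 FPKM in mimic 3, and at 85.3 and 73.6 FPKM in control 1 and 2 but at 59.5 FPKM in control 3. KDM1A, a histone demethylase, was at 65.8, 60.5 and 84.0 FPKM in mimic 1, 2 and 3 and at 87.2, 81.3 and 63.9 FPKM in control 1, 2 and 3. EZH2 is a histone methyltransferase, and its 3' UTR as searched, of 262 nt, has no AGCAATA match, unlike that of KDM1A. It was at 13.5, 12.5 and 16.9 FPKM in mimic 1, 2 and 3 and at 16.9, 17.5 and 13.6 FPKM in control 1, 2 and 3. CDK6, KDM1A and EZH2 went against the label of mimic 3 and of control 3, so every direction given here is between libraries as labelled. As labelled, log2 differences were -0.14 for CDK6, -0.15 for KDM1A, -0.16 for EZH2 and -0.15 for MITF, each with an adjusted p of 0.999 from limma. MIR137HG, the host gene of the microRNA, differed by -0.03 with the same adjusted p.

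**Figure D1:**
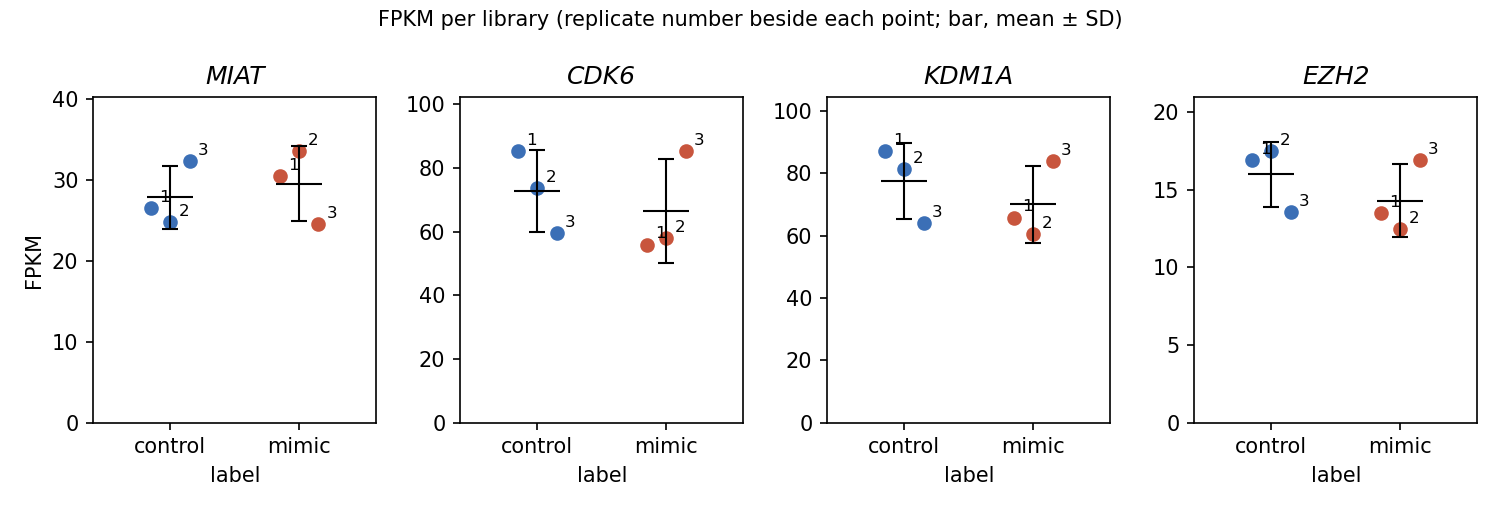
FPKM of MIAT, CDK6, KDM1A and EZH2 in each library by its label, with the replicate number beside each point and bars for the mean and SD of 3 libraries. CDK6 is at 85.1 FPKM in mimic 3 and 59.5 FPKM in control 3, on the far side of the other libraries with the same label.

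Across all genes, limma called 0 of 13475 genes higher or lower in libraries labelled mimic. The smallest adjusted p was 0.29, and 275 genes had an unadjusted p under 0.05, where 673.75 would be expected by chance. The groups did not overlap for 418 genes higher and 281 lower in the mimic libraries, 5.19% of the genes, where chance gives 10%. The smallest p belonged to DMC1, a recombinase of meiosis, at 0.30 ± 0.15 FPKM (SD, n = 3) against 1.63 ± 0.21 FPKM (SD, n = 3) in control, a log2 difference of -1.43 ± 0.19 (SE) with an adjusted p of 0.29 from limma. TMEM160 followed, at 8.98 ± 0.64 FPKM (SD, n = 3) against 4.87 ± 0.58 FPKM (SD, n = 3), a log2 difference of 0.82 ± 0.11 (SE) with the same adjusted p. Log2 differences of GPR27, RMRP, INTS6-AS1, PTRHD1, PTENP1-AS, CMTM1, WBSCR27, GLUD1P7 and RNF166 ran from 0.35 for RNF166 to 1.003 for GLUD1P7. Those of FLJ42351, PLAC8L1, MID1IP1-AS1, INE1, MGP, PURG, U2AF1L4, SOHLH2 and IL18BP ran from -0.96 for FLJ42351 to -0.33 for PURG, and the adjusted p of each of these 2 sets of genes was 0.999. Without mimic 2, limma called 1 gene, and without both replicates 3, a choice made after the data were seen, it called 17.

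With camera, 4 of the 22 tested lists differed between the labelled groups. Genes of mitosis and G2/M were lower in libraries labelled mimic, with 29 of 30 members lower, a median log2 difference of -0.09 and an adjusted p of 0.00018 (adjusted p = 0.78 with an estimated correlation). Their median against the mean of the 6 libraries was 0.060 in mimic 3 and -0.073 in control 3, each opposite to the label. In that list the ubiquitin-conjugating enzyme UBE2C was at 201 against 194 FPKM in control and the securin PTTG1 at 187 against 201 FPKM. Genes of DNA replication and G1/S were lower, with 28 of 31 members lower, a median of -0.08 and an adjusted p of 0.0072 (adjusted p = 0.78 with an estimated correlation), and they too lay opposite to the label in mimic 3, at 0.066, and control 3, at -0.086. The sliding clamp PCNA was at 229 against 245 FPKM in control and CCND1, cyclin D1, at 234 against 217 FPKM. Replication-dependent histones were higher, with 14 of 16 tested members higher, a median of 0.14 and an adjusted p of 0.0043 (adjusted p = 0.78 with an estimated correlation), and were at -0.11 in mimic 3 and 0.034 in control 3, again opposite to the label. HIST3H2A was at 31.9 ± 4.47 FPKM (SD, n = 3) against 19.2 ± 14.0 FPKM (SD, n = 3) in control and HIST1H2BK at 20.9 against 19.3 FPKM; histone gene copies are alike in sequence, so reads may be split among them. Reported miR-137 targets were lower, with 23 of 27 tested members lower, a median of -0.11 and an adjusted p of 0.0082 (adjusted p = 0.78 with an estimated correlation). YBX1, an RNA-binding protein, was at 942 against 1081 FPKM in control and CSE1L, a nuclear export factor, at 91.0 against 97.6 FPKM. No member of these 4 lists passed the threshold over all genes, and 0 passed when adjusted over the list alone. Fry gave an adjusted p of 0.863 for each of the 4 lists. The call of the reported targets was lost without control 1 (adjusted p = 0.44), control 2 (0.40), mimic 1 (0.67) or mimic 2 (0.46), and with no filter (0.052). It was stronger without control 3 (6.4e-06), mimic 3 (1.2e-06) or both (7.2e-10), where the adjusted p with an estimated correlation was 0.74, 0.68 and 0.35, and fry gave 0.048 without both. That of DNA replication was lost without the same libraries, at 0.31, 0.37, 0.11 and 0.45, and without control 3, mimic 3 or both it was stronger, at 5.3e-05, 0.00019 and 9.1e-06, with the same adjusted p as the reported targets with an estimated correlation and from fry. The calls of mitosis and of histones were each lost without control 1, at 0.23, and without mimic 2, at 0.091, and that of histones with no filter, at 0.063. Without control 3, mimic 3 or both, the adjusted p of mitosis was 1.1e-05, 2.9e-06 and 1.2e-06 and that of histones 0.0015, 0.0012 and 0.0016. With an estimated correlation the adjusted p of each was 0.74, 0.68 and 0.62 in these settings. Leaving out both was chosen after the data were seen. In that setting the estimated correlation of the reported targets was 0.0010, below the preset 0.01. The loss of their call there therefore does not show that correlated genes made it. The estimated correlation was 0.049 for DNA replication, 0.30 for mitosis and 0.18 for histones.

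**Figure D2:**
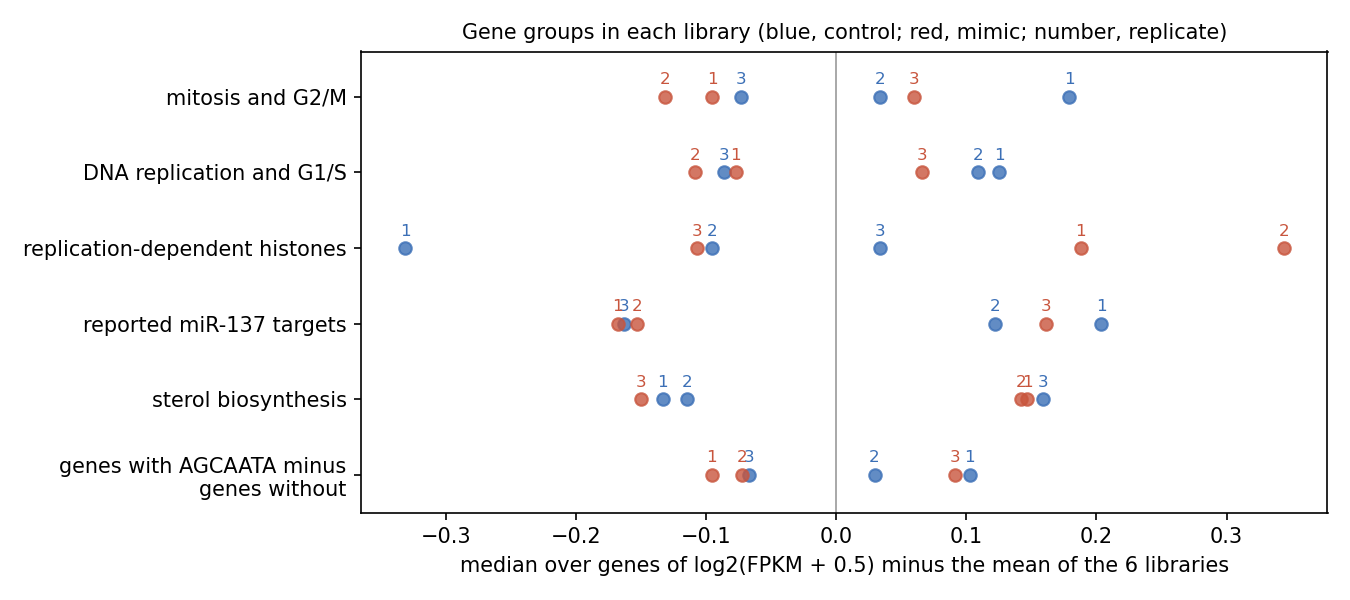
Each point is 1 library; the horizontal axis is the median over the genes of a group of log2(FPKM + 0.5) minus the mean of the 6 libraries, and for the bottom row that median for genes with AGCAATA minus that for genes without. The reported targets lie at -0.17, -0.15 and -0.16 in mimic 1, mimic 2 and control 3 and at 0.16, 0.20 and 0.12 in mimic 3, control 1 and control 2.

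Sterol biosynthesis genes were not called, with 19 of 23 tested members higher and an adjusted p of 0.064 from camera. The list passed, as higher, with a pseudocount of 1 (0.048), a filter at FPKM 1 (0.045), quantile normalization (0.025), without control 3 (7.7e-05), without mimic 3 (0.00019) and without both replicates 3 (3.0e-07). In these settings the adjusted p with an estimated correlation ran from 0.35 without both replicates 3 to 0.89 with quantile normalization, so none passed with that test. That test called 0 lists in any of the 15 settings in which it was run. Without both replicates 3 the list's estimated correlation was 0.032, near the preset 0.01. The loss there therefore does not show that correlated genes made the call. Their medians were 0.15, 0.14 and -0.15 in mimic 1, 2 and 3 and -0.13, -0.11 and 0.16 in control 1, 2 and 3. FDFT1, squalene synthase, was at 157 against 144 FPKM in control and FDPS at 260 against 265 FPKM. Lists of neural identity and function did not pass with all 6 libraries: camera's adjusted p was 0.55 for adrenergic neuroblastoma identity, 0.13 for mesenchymal neuroblastoma identity, 0.91 for neuronal cytoskeleton and differentiation, 0.57 for synaptic vesicle release and 0.68 for schizophrenia risk genes. Mesenchymal identity genes passed, as lower, without control 3 (0.039), without mimic 3 (0.0051) and without both replicates 3 (0.0051). With an estimated correlation the adjusted p was 0.74, 0.68 and 0.35 in these settings, and fry gave 0.048 without both replicates 3. Their estimated correlation there was -0.059, so this loss too does not show that correlated genes made the call. MYCN, the amplified oncogene of many neuroblastomas, was at 2265 ± 124 FPKM (SD, n = 3) against 2317 ± 62.3 FPKM (SD, n = 3) in control. CHGA was at 1108 against 1101 FPKM, VIM at 291 against 302 FPKM, TWIST1 at 71.5 against 74.7 FPKM, UCHL1 at 965 against 916 FPKM and STMN2 at 552 against 581 FPKM. The synaptic genes SNAP25 and SYT11 were at 103 against 109 FPKM and 101 against 93.0 FPKM, and the schizophrenia risk genes RGS4 and TCF4 at 178 against 196 FPKM and 65.3 against 70.6 FPKM.

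RNA regulators did not pass with all 6 libraries either, with camera's adjusted p at 0.20 for nuclear and regulatory lncRNAs, 0.91 for splicing factors linked to MIAT, 0.74 for Polycomb repressive complexes and 0.54 for the small RNA silencing machinery. The lncRNAs passed, as lower, without control 3 (0.029), without mimic 3 (0.030) and without both replicates 3 (0.0070), and with an estimated correlation the adjusted p was 0.74, 0.68 and 0.35 in these settings. Without both replicates 3 their estimated correlation was -0.016, so the loss there does not show that correlated genes made the call. GAS5 was at 913 against 948 FPKM in control, SNHG5 at 663 against 702 FPKM, SRSF2 at 189 against 195 FPKM and SRSF3 at 146 against 151 FPKM. RBBP7 and PHF19 of the Polycomb complexes were at 102 against 105 FPKM and 57.3 against 56.0 FPKM, and CNOT7 and XPO5 at 88.8 against 87.0 FPKM and 47.3 against 46.8 FPKM. For stress and signalling, the adjusted p was 0.64 for the interferon response, 0.20 for the p53 response, 0.55 for the unfolded protein and integrated stress response and 0.13 for immediate early genes, which passed, as higher, without control 3 (0.011) and without both replicates 3 (0.018). With an estimated correlation the adjusted p of these genes was 0.74 and 0.68 in these settings. IFIT5 was at 10.9 against 10.5 FPKM, CCNG1 at 65.1 against 67.0 FPKM, BAX at 64.9 against 59.3 FPKM, ATF4 at 471 against 480 FPKM, HSP90B1 at 261 against 263 FPKM, KLF6 at 27.7 against 25.9 FPKM and JUN at 26.5 against 21.2 FPKM. For metabolism and translation, it was 0.55 for glycolysis and hypoxia, 0.20 for the nuclear-encoded respiratory chain and 0.13 for cytosolic ribosomal proteins. GAPDH was at 3344 against 3467 FPKM, TPI1 at 610 against 621 FPKM, COX7C at 1011 against 1096 FPKM, ATP5B at 615 against 622 FPKM, RPS18 at 5660 against 5846 FPKM and RPLP1 at 4802 against 4780 FPKM. Ribosomal proteins and the respiratory chain passed, as lower, without mimic 1 (4.01e-07 and 9.3e-05) and without control 1 (0.0011 each), and with an estimated correlation the adjusted p of both was 0.92 and 0.89 in these settings.

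Markers of other cell types had an adjusted p of 0.30 from camera over 7 tested genes, with DCN at 31.3 against 34.1 FPKM in control and PDGFRB at 20.7 against 21.1 FPKM. Of the Schwann and glial markers, 4 were tested, too few for a set test, with PMP22 at 11.1 against 11.8 FPKM and SLC1A3 at 2.38 against 2.102 FPKM. Of 13 mitochondrially encoded genes, 0 were found in the table under the symbols used. In every list, 0 members passed over all genes and 0 passed when adjusted over the list alone.

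Genes with a miR-137 seed site were compared with genes without one, a measure of direct targets that does not rest on earlier reports of targets. Of the 12126 genes searched, 1602 had AGCAATA, and their median log2 difference was lower than that of the other 10524 genes by the small amount of -0.045. AGCAATA ranked 2 from the lowest of the 210 orderings, with GCAATAA alone slightly lower. However, AGCAATA lay within 2 places of an end in every single library and in each of the 10 splits into 3 against 3. The rank therefore says nothing about the labels. Camera gave p = 0.00015, and p = 0.41 with an estimated correlation. The 673 genes with the longer site AGCAATAA differed by -0.053. Per library, genes with AGCAATA minus genes without stood at -0.096, -0.072 and 0.091 in mimic 1, 2 and 3 and at 0.10, 0.030 and -0.067 in control 1, 2 and 3, so mimic 3 and control 3 again lay opposite to their labels. Without control 1 the difference was -0.0078 and camera no longer passed its threshold. Without mimic 1 it was -0.016 and camera did not pass either, and without mimic 2 it was -0.020. Without control 3 and without mimic 3 it was -0.087 and -0.10, and without both replicates 3, a choice made after the data were seen, -0.14.

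Libraries did not group by label over all tested genes. The first principal component held 43.2% of the variance and placed mimic 1, mimic 2 and control 3 at 12.6, 15.7 and 11.2, and mimic 3, control 1 and control 2 at -11.1, -20.1 and -8.29. Control 3 correlated best with mimic 1 (Pearson's r = 0.9941 across genes, which are not independent replicates), and mimic 3 with control 2 (r = 0.9932).

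**Figure D3:**
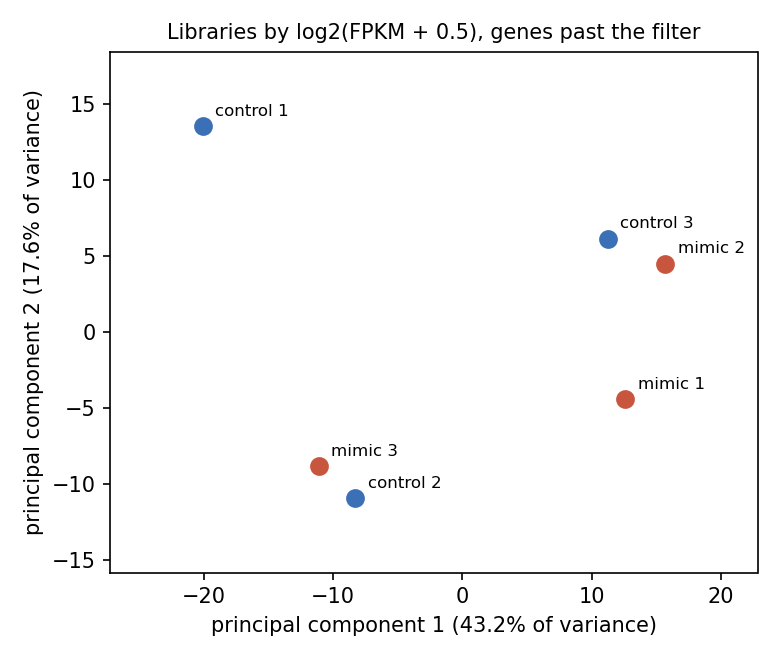
Principal components 1 and 2 of log2(FPKM + 0.5) over the tested genes, holding 43.2% and 17.6% of the variance, with 1 point for each library coloured by its label. Control 3 lies at 11.2 on the first component beside mimic 1 and mimic 2, and mimic 3 at -11.1 on the side of control 1 and control 2.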

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

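The choices to leave out both replicates 3, and to run the other set tests under each alternative, were made after the data were seen. Of 1578 values recomputed under alternatives, 1454 kept their direction and side of the threshold, moved by less than the spread or, for counts, differed little. The values include each named gene, and no named gene passed with all 6 libraries. For those genes little change was likely in advance, so the share does not measure how well the called lists held. Limma called 0 genes, and 0 under the alternatives except 1 with no filter, 1 without mimic 2 (range 0 to 1 leaving out each library) and 17 without both replicates 3. The MIAT difference ranged from -0.017 without mimic 2 to 0.21 without mimic 3 when 1 library was left out, and was 0.31 without both replicates 3. That of MIR137HG ranged from -0.17 to 0.13 when 1 library was left out. Camera called 4 lists, against 0 with an estimated correlation, 0 with fry, 2 with no filter, 8 without both replicates 3, and 0 without mimic 2 to 8 without control 3. Under each of the alternatives, 0 lists passed with an estimated correlation, and 0 with fry except 3 without both replicates 3. As the test with an estimated correlation called 0 lists in any of 15 settings, it does not tell which calls came from correlated genes. These counts do not say which lists: the 2 without control 1 were ribosomal proteins and the respiratory chain. The cause of these shifts was not tested. The seed-site difference stayed below 0 under every alternative run.

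Lists not called with all 6 libraries changed direction under these alternatives, given as adjusted p. Without both replicates 3 it was 0.62 for splicing factors, 0.51 for synaptic vesicle release, 0.44 for glycolysis and 0.66 for the respiratory chain. For neuronal cytoskeleton it was 0.91 with a filter at FPKM 1 and 0.71 with quantile normalization, for ribosomal proteins 0.81 with quantile normalization, and for interferon response 0.896 with no filter. For lists that changed direction when some library was left out, the adjusted p over leaving out each one ranged from 0.45 to 0.82 for schizophrenia risk genes, 0.67 to 0.96 for splicing factors, 0.12 to 0.96 for adrenergic identity, 0.79 to 0.96 for neuronal cytoskeleton, 0.45 to 0.93 for synaptic vesicle release and 0.43 to 0.88 for the stress response. The range was 0.11 to 0.86 for glycolysis, 9.3e-05 to 0.85 for the respiratory chain, 4.01e-07 to 0.97 for ribosomal proteins and 0.27 to 0.67 for silencing machinery. The lowest values of the respiratory chain and of ribosomal proteins were calls in the same direction as with all libraries.

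With a replicate block, limma called 0 genes, with 191 at an unadjusted p under 0.05, and the MIAT difference was 0.08. Deviations of libraries with the same number correlated at -0.24, -0.18 and -0.47, and no library correlated best with its own number. Libraries with the same number lay on opposite sides of the first principal component, and that difference enters these correlations. The correlations therefore cannot decide whether the numbers pair the libraries. A count test on whole reads recovered from FPKM was not run, since the step of 1 fragment depends on each gene's length. The estimated depths limit low genes most.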

Other observations

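The tests of gene counts, list counts and ribosomal RNA across splits or libraries, of 3' UTR terms and of components 3 to 5 were chosen after at least part of their result was seen, and so was the choice to leave out both replicates 3. Without those libraries, limma called 17 genes in 2 libraries labelled mimic against 2 labelled control, and each of the 17 was higher. Among them, named here after their values were seen and with no test of a shared function, were TPPP3 at a log2 difference of 1.64 ± 0.12 (SE), STMN4 at 1.27 ± 0.10, MAP6 at 1.14 ± 0.12 and TPPP at 0.97 ± 0.12. SQSTM1 was at 0.70 ± 0.083 and AKR1C3 at 1.47 ± 0.10. The largest difference was that of CNGB1, at 2.25 ± 0.17, and SLC6A17, MAPK15 and KLHDC8B were at 1.42, 1.26 and 1.23. The libraries left out were doubted because of their values, so this count is exploratory.

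The 6 libraries make 10 splits into 3 against 3, too few for a share under 0.05. As labelled, limma called 0 genes, which all 10 of 10 splits reach by construction, so that number says nothing about chance; the highest of the others called 1961. That split sets mimic 1, mimic 2 and control 3 against mimic 3, control 1 and control 2, and no other split called more than 2 genes, which points to a structure of the libraries. Camera called 4 lists as labelled, a number that 7 of the 10 splits reached, with 8 as the highest other. The seed-site difference was -0.045 as labelled, and 5 of the 10 splits lay as far from 0 in either direction, with -0.15 as the highest other, in the same split that called 1961 genes.

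The libraries did not separate by their label, and a candidate explanation is that the labels of mimic replicate 3 and control replicate 3 were exchanged, a hypothesis found in these data and tested on the same libraries. For mimic 1, mimic 2 and control 3 against the others, AGCAATA ranked 1 from the lowest of 210 orderings, at -0.15, but it lay within 2 places of an end in each of the 10 splits, so that rank decides nothing. The tables argue against a leading difference unrelated to miR-137, since AGCAATA ranked 1 from the lowest of 16384 heptamers along the first component. It ranked 1948 to 8496 along components 2 to 5, in both cases without 3' UTR terms. Each component was signed so that CDK6, which has a site, falls. Residual ribosomal RNA is also argued against, as RNA18S5 was higher in 4 of 9 pairs of the first 3 libraries with the others. That order was broken by mimic 3 and by control 3, the libraries whose labels are in doubt. As labelled, RNA18S5 was higher in each mimic library than in each control library. The nearest values were 2.32 FPKM in mimic 1 and 2.18 FPKM in control 2. Length and base composition of the 3' UTR did not account for the whole AGCAATA coefficient along the first component. It went from -0.0059 to -0.0042 ± 0.00021 (SE over genes, which are not independent) with both as terms. That is below the -0.0018 of the lowest ordering that is not a site. The second component met the same criterion, at -0.0020 against -0.0013, so that criterion does not set the first component apart. With these terms AGCAATA ranked 3 of 16384 heptamers along the first component and 61 along the second. The contrast between these components is thus smaller with terms. Along components 3, 4 and 5 it ranked 2568, 16055 and 2131. In each of the 10 splits, which all share in the first component, it lay within 15 places of an end. An exchange stays open, as do 2 separate errors, such as a failed transfection and a carry-over of mimic. If differing depth acted on genes without regard to miR-137 sites, the heptamer rank would argue against it as the whole cause. That rank was not set up to test depth, so depth stays undecided. The order of depths by itself decides nothing. The first 3 libraries were deeper in 3 of 9 pairs through control 3 alone, at about 15.3 M fragments, and mimic 1 and mimic 2 were the shallowest. The labels were used as given.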
